A study of Bos taurus with 15 samples.

How the data were processed

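Mesenteric fat, the visceral fat that lies along the intestine, was profiled in crossbred beef steers (Bos taurus) kept for 78 days on a concentrate-rich ration that included WDGS. Per the labels, 16 steers were selected as the animals farthest from the mean of both traits in the 4 quadrants of weight gain and feed intake. Arrays of 15 of them were analysed here, 1 array per steer, with 4 steers in each of the groups high gain-high intake (HGHI), high gain-low intake (HGLI) and low gain-low intake (LGLI) and 3 in the group low gain-high intake (LGHI). The remaining steer was not analysed here. Replicate numbers only name the arrays and pair no animals. Each steer is a separate animal, so the errors measure differences between animals plus those between single arrays. Gain and feed intake were not measured on the arrays, and their values per animal were not used here.

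Per the labels' protocols, total RNA was extracted with TriPure Reagent and spin columns, and biotin-labelled cRNA was made from 250 ng of it with the standard Affymetrix protocol. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console, without version or algorithm. The background correction, normalization and array design were not given in the sources used here. The values deposited by the authors were read as log2 expression values, 1 column per array. This reading rests on the values themselves, which ran from 3.25 to 19.685 with none missing, and the base of the logarithm is not stated. Every fold change below assumes base 2. Array medians lay between 7.97 and 8.07 and array maxima between 19.571 and 19.685, so the arrays had been brought to a nearly common scale, and the most abundant transcripts lay at the top of the measured range. No detection p was used, so the level of the background is unknown, and the number of arrays limits the precision.

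The table held 26773 probes, all of them tested. The platform annotation gave exactly 1 gene symbol for 18790 probes (18444 genes, 320 of them with more than 1 probe), several symbols for 385 and none for 7598. Of the probes with 1 symbol, 18003 were matched by gene number to the RefSeq annotation of the assembly ARS-UCD2.0, and 0 symbols changed. The build behind the array design was not given in the sources used here, so no coordinates are printed. In 114 sets, probes carried identical values on every array (309 probes, 195 of them redundant), so counts of probes are not counts of independent measurements. Correlations between arrays ran from 0.966 to 0.987 over 105 pairs, and 0 pairs of arrays were identical.

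The tests, their thresholds, the gene lists and the rule for naming genes were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes without trend), with 11 residual and 3.23 prior degrees of freedom. The 4 main contrasts were gain (mean of HGHI and HGLI minus mean of LGHI and LGLI), intake (mean of HGHI and LGHI minus mean of HGLI and LGLI), the interaction (HGHI minus LGHI, less HGLI minus LGLI) and efficiency (HGLI minus LGHI, the steers with most gain for the feed eaten against those with least). The 4 simple contrasts compared pairs of groups that shared 1 trait level. All contrasts use the same 15 arrays and are not independent of each other. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes, and all tests were two-sided. Where fewer than 5 probes passed in a direction, genes with an unadjusted p under 0.01 and the largest differences filled that direction up to 5. Uncharacterised loci and small RNAs were passed over. Up to 4 members with the smallest p were taken from each called list, and 16 adipose genes were reported whatever their values.

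Gene lists comprised 25 pathways and 21 marker sets of cell types that a piece of mesenteric fat could hold, 46 in all. The list called glycolysis below also holds genes of gluconeogenesis. Each was tested with limma's camera on 1 probe per gene (the probe with the highest mean) with a preset correlation between genes of 0.01, adjusted over the 46 lists of a comparison. The same test with a correlation estimated from the residuals, the test fry and, on the list scores, an exact permutation test of the steers were run beside it. A list score is the mean over the members of the value minus that gene's mean over all arrays. Members were also tested "adjusted over the list alone", with the Benjamini-Hochberg adjustment over that list's members only. The extracellular matrix list shares 5 members with the preadipocyte and fibroblast list, so calls of these lists are not independent.

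The procedure was tested on simulated data for the gain comparison with 200 of the 26773 probes shifted. A shift of 0.5 on the log2 scale was recovered for 26.5% of them with 1 false call, a shift of 1 for 84.5% with 9 and a shift of 2 for 100% with 5. With 0 probes shifted there were 0 calls. A list of 15 members shifted by 0.5 was called, along with 0 of the other 45 lists. The simulated probes varied independently of each other, so these runs cannot show how many false calls correlated genes give. Among other splits of the real steers for gain, described below, the median number of lists called was 11. The alternatives were quantile normalization, centring on array medians, leaving out the lowest 25% of probes, only probes with 1 symbol, trended robust or no moderation, array weights, a looser threshold of 0.1, single-factor and pairwise models, the mean of a gene's probes, and leaving out each array in turn. Fits without the 3 arrays highest for mesothelium markers, without the 2 arrays lowest for the lipogenesis list, and with the standard deviation of each array's values as a covariate were added after seeing the data.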

Results

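Expression in mesenteric fat was measured on 15 arrays, each from a different steer: 4 HGHI, 4 HGLI, 4 LGLI and 3 LGHI. Each array gave log2 expression values for 26773 probes, with array medians between 7.97 and 8.07. The study asked which transcripts of this fat differ between cattle that differ in feed efficiency. Group values below are means ± SD over the 4 steers of a group (3 in LGHI), differences are on the log2 scale with the standard error of the fit, and p-values of genes and lists are adjusted. Over all probes, 0 passed an adjusted p of 0.05 in any of the 8 contrasts tested with limma, so named genes are described by their values.

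Between high and low gain, averaged over intake, the named genes below are those with the largest differences among genes with an unadjusted p under 0.01, as for the comparisons that follow. The larger values in high gain steers included 4 genes of contractile muscle. MYH11, the smooth muscle myosin heavy chain, was 7.56-fold higher (2.92 ± 0.83), at 15.96 ± 1.26 in HGHI and 14.62 ± 2.31 in HGLI against 12.45 ± 1.66 in LGHI and 12.29 ± 1.83 in LGLI. Desmin (DES), a muscle intermediate filament protein, was 7.38-fold higher (2.88 ± 0.74), CNN1, which encodes calponin, 4.86-fold (2.28 ± 0.74) and PLN, which encodes the calcium pump regulator phospholamban, 3.78-fold (1.92 ± 0.54). In each of these 4 genes, 7 of the 8 high gain steers lay above the low gain mean. KCNAB1, a potassium channel subunit, was 3.61-fold higher (1.85 ± 0.27), with 8 of 8 high gain steers above that mean. By the same rule, the largest lower values in the high gain steers were those of IL18BP, a secreted binder of interleukin-18 (-1.25 ± 0.34, 2.38-fold), SNCG, gamma-synuclein (-1.19 ± 0.30, 2.28-fold), and ANGPTL4, an inhibitor of lipoprotein lipase (-1.06 ± 0.27, 2.08-fold). The cyclin CCND2 (-0.96 ± 0.26) and the matrix glycoprotein EMILIN2 (-0.72 ± 0.19) were next among genes with an unadjusted p under 0.01.

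None of these genes passed the threshold over all probes: adjusted p was 0.0976 for KCNAB1 and lay between 0.381 and 0.444 for the others. With limma, 0 of 26773 probes passed for gain, while 2629 had an unadjusted p under 0.05, where chance gives 1339. An unadjusted p under 0.01 was reached by 588 probes, 233 higher and 355 lower with high gain, against 268 by chance. The lowest adjusted p, 0.0871, belonged to PDLIM3, a LIM protein that binds alpha-actinin, which is named here after its values were seen: 1.42 ± 0.19 (2.67-fold), from 13.26 to 14.29 in high gain and from 11.92 to 13.03 in low gain steers. It was among 10 probes (4 higher, 6 lower) whose high and low gain steers did not overlap, where chance gives 8.32 (0.0311% of the probes). PDLIM3 passed with array centring (adjusted p = 0.0434), with only probes of 1 symbol (0.0411, together with KCNAB1 at 0.0468), with gain as the only factor (0.0348), without LGLI 4 (0.0377) and without the 3 arrays highest for mesothelium markers (0.0135). KCNAB1 passed without HGLI 4 (0.0198), and over all 27 alternatives the lowest adjusted p of the gain comparison ran from 0.0135 to 0.305.

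**Figure D1:**
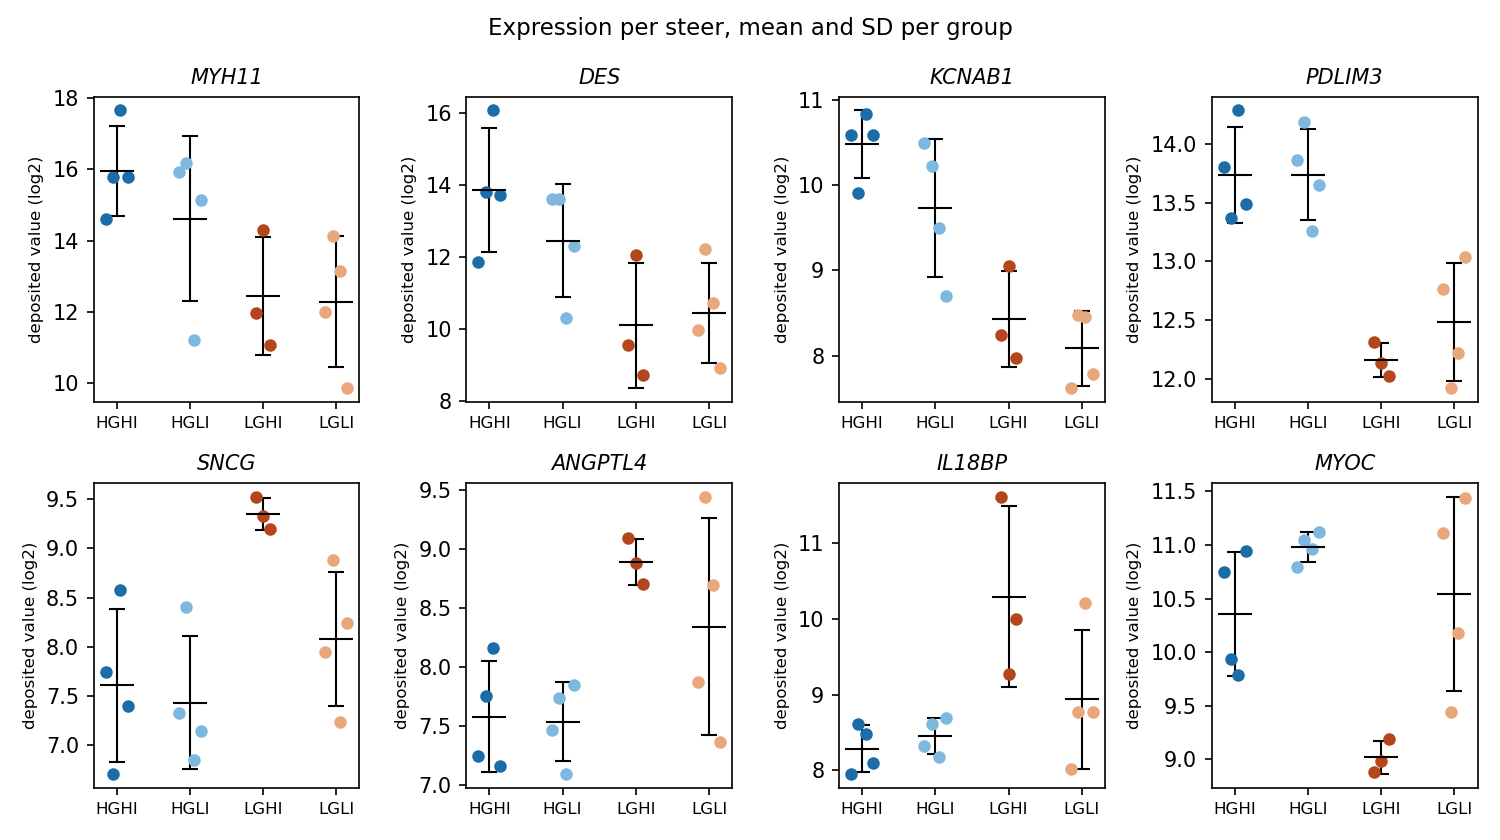
Log2 expression value of 8 genes (vertical axes) in each steer (points), by group (horizontal axes), with the group mean ± SD as bars. MYH11 and DES spread over several log2 units within every group, while PDLIM3 in the 8 high gain steers (13.26 to 14.29) lay above the 7 low gain steers (11.92 to 13.03).

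Among the gene lists, 9 were higher and 2 lower with high gain in camera with its preset correlation. None of the 11 was called when the correlation was estimated (lowest adjusted p = 0.689 with an estimated correlation). The smooth muscle and pericyte markers had the largest mean difference, 1.09, with 11 of 12 measured members higher and 1 lower. Of these, 6 passed when adjusted over the list alone (MYH11, TAGLN, CNN1, DES, MYLK and SYNM) and 0 over all probes. SYNM, the intermediate filament protein synemin, differed by 0.90 ± 0.19 and TAGLN, transgelin, by 1.26 ± 0.41. Oxidative phosphorylation genes were 0.39 higher on average, 29 of 30 in that direction, for example UQCRB of complex III (0.53 ± 0.18) and NDUFS1 of complex I (0.63 ± 0.24). Lipogenesis genes were 0.56 higher, 16 of 17, among them ACACA, acetyl-CoA carboxylase (1.34 ± 0.59), ACLY, ATP citrate lyase (1.59 ± 0.78), and SLC25A1, the mitochondrial citrate carrier (1.21 ± 0.55). Smaller mean differences came from glycolysis (0.20, 16 of 20 higher, for example ALDOA at 0.69 ± 0.25), oxidative stress and glutathione (0.27, 18 of 23, GSTM2 at 0.72 ± 0.29), ribosomal proteins (0.13, 24 of 27, RPL27 at 0.35 ± 0.11), the unfolded protein response (0.13, 14 of 17), preadipocyte and fibroblast markers (0.29, 13 of 15) and extracellular matrix genes (0.17, 21 of 28). The mean matrix score was 0.03 in HGHI, 0.10 in HGLI, 0.16 in LGLI and -0.37 in LGHI. In the same order, preadipocyte scores were 0.04, 0.18, 0.18 and -0.53, and unfolded protein response scores 0.02, 0.09, 0.02 and -0.17. For each of these lists only LGHI lay low. So it was for lipogenesis, at -0.70 in LGHI and between 0.05 and 0.26 in the other groups. For matrix, 4 of 8 high gain steers lay above the low gain mean. The lower lists were macrophage and monocyte markers (-0.36, 16 of 17 lower, for example the scavenger receptor MSR1 at -0.57 ± 0.25 and VSIG4 at -0.87 ± 0.34) and cytotoxic lymphocyte markers (-0.14, 11 of 16 lower, for example granzyme A, GZMA, at -0.39 ± 0.11). Mean macrophage scores were -0.54 in HGHI, 0.18 in HGLI, 0.41 in LGLI and -0.06 in LGHI, so HGLI lay above LGHI. For macrophages, 7 of 8 high gain steers lay below the low gain mean, but only 3 of 7 low gain steers above the high gain mean. Cytotoxic lymphocyte markers were faint, with a median level of 7.42. All probes in the bin at a median level of 7.29 had a median gain difference of -0.07.

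Adjusted over the list alone, the other passing members were DNAJC3, a chaperone partner of the endoplasmic reticulum (0.57 ± 0.13), GZMA and KLRF1, and over all probes 0 members of any list passed. Camera's adjusted p was 7.09e-09 for smooth muscle, 1.64e-10 for oxidative phosphorylation, 0.00147 for ribosomal proteins, lipogenesis and oxidative stress, 0.00231 for preadipocyte and fibroblast markers, 0.0224 for macrophages, cytotoxic lymphocytes and glycolysis, 0.0373 for the unfolded protein response and 0.0446 for extracellular matrix. All 11 calls rest on the preset correlation: adjusted p = 0.689 with an estimated correlation for each, except 0.72 for macrophages. The lowest exact permutation p of a list score was 0.0102 (0.469 adjusted). The score of mesothelium markers was high in HGLI 3 (2.02), LGLI 1 (1.21) and LGLI 4 (1.81), and LGLI 4 also had the highest macrophage score (1.94). Leaving out single steers ended 7 of the 11 calls: lipogenesis (0.34; 0.85 without HGHI 3, still called) and preadipocytes (0.15) without LGHI 1, glycolysis without any of 4 steers and matrix without any of 7 (both 0.09 without LGHI 1), macrophages without any of 6 (-0.10 without LGLI 4), cytotoxic lymphocytes without LGLI 4 (-0.09) or LGHI 3 (-0.11), and the unfolded protein response without any of 9 (0.09 without LGLI 3). Values that moved while still called were 0.32 for glycolysis without HGHI 3, -0.54 for macrophages without HGLI 3 and 0.19 for preadipocytes without HGHI 1, and ACACA was at 0.88 without LGHI 1. With the standard deviation of array values as a covariate, the smooth muscle call alone was kept (1.56), whereas lipogenesis came to 0.04, oxidative phosphorylation to 0.11, cytotoxic lymphocytes to -0.03 and glycolysis turned to -0.027.

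Between high and low intake, averaged over gain, PTN had the largest lower value with high intake among genes with an unadjusted p under 0.01, followed by GAS1, TGFBI, ERRFI1 and CFD. PTN, the heparin-binding growth factor pleiotrophin, was 4.35-fold lower with high intake (-2.12 ± 0.66), at 12.87 ± 1.31 in HGHI and 11.84 ± 1.29 in LGHI against 14.49 ± 0.80 in HGLI and 14.47 ± 2.05 in LGLI. GAS1 (growth arrest specific) was 3.21-fold lower (-1.68 ± 0.55), TGFBI, a matrix protein induced by TGF-beta, 2.38-fold (-1.25 ± 0.36), ERRFI1, an inhibitor of the EGF receptor, 2.31-fold (-1.21 ± 0.38) and CFD, the adipokine adipsin, 2.18-fold (-1.12 ± 0.36). For GAS1, ERRFI1 and CFD, 7 of 7 high intake steers lay below the low intake mean. However, for each of these genes and for PTN the 3 highest of all steers were HGLI 3, LGLI 1 and LGLI 4. These 3 steers were also highest for mesothelium markers. Without these 3 the differences were -0.68 for GAS1, -0.49 for ERRFI1, -0.58 for CFD, -1.30 for PTN and -1.05 for TGFBI. The genes with the largest higher values under the same limit on p were 4 olfactory receptor genes near the bottom of the measured range, among them OR5H33 (0.75 ± 0.18) and OR8B1AN (0.57 ± 0.11), and RGS7, a regulator of G protein signalling (0.66 ± 0.17, and 0.41 without those 3 steers). OR5H33 was at 7.06 ± 0.43 in LGHI and between 5.69 and 5.92 in the other groups. None of the 10 passed, with adjusted p from 0.453 to 0.691. With limma, 0 probes passed for intake, and 1886 had an unadjusted p under 0.05.

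Complement genes were lower with high intake in camera by a mean difference of -0.87, 16 of 18 in that direction. With an estimated correlation neither this list nor any other was called (lowest adjusted p = 0.627 with an estimated correlation). Of the complement genes, 3 passed adjusted over the list alone, SERPING1, the C1 inhibitor (-0.95 ± 0.27), the protease C1S (-0.60 ± 0.20) and CFD, and 0 over all probes. C3, the central complement component, differed most (-2.81 ± 1.17). Preadipocyte and fibroblast markers (-0.43, 13 of 15 lower, for example dermatopontin, DPT, at -0.71 ± 0.24), extracellular matrix genes (-0.30, 21 of 28, POSTN at -2.03 ± 0.92) and macrophage markers (-0.59, 15 of 17, CSF1R at -0.84 ± 0.38) were lower too. So were mesothelium markers (-0.84, 11 of 16, mesothelin, MSLN, at -1.45 ± 0.64), interferon response genes (-0.19, 23 of 26), lipogenesis genes (-0.39, 15 of 17) and clock genes (-0.16, 13 of 15, NR1D1 at -0.51 ± 0.23). The mean lipogenesis score was 0.22 in HGHI, 0.26 in HGLI, 0.05 in LGLI and -0.70 in LGHI. For this list, as for the matrix and preadipocyte scores given above, the difference lay mainly with LGHI. Past the threshold adjusted over the list alone were IFIT5 (-0.53 ± 0.14) among the interferon genes and the desaturases FADS1 (-0.59 ± 0.18) and FADS2 (-0.79 ± 0.22) among the lipogenesis genes. Smooth muscle markers (0.37, 11 of 12 higher) and liver markers (0.06, 11 of 13 higher) lay higher, with 0 members past the threshold adjusted over the list alone. Liver markers were faint, with a median level of 7.08. All probes in bins at median levels of 6.86 and 7.29 had median intake differences of 0.055 and 0.043, close to that of the liver list.

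Camera called these 10 lists with adjusted p of 1.86e-06 (complement), 1.12e-05 (preadipocytes), 0.000604 (interferon), 0.000789 (macrophages), 0.000981 (matrix), 0.00525 (lipogenesis), 0.0208 (mesothelium), 0.041 (clock) and 0.0457 (liver and smooth muscle). With an estimated correlation none was called: adjusted p = 0.627 for complement, preadipocytes, matrix, clock and liver, 0.754 for interferon, 0.757 for macrophages and 0.791 for lipogenesis, mesothelium and smooth muscle. The lowest exact permutation p was 0.022 (0.529 adjusted). The 3 steers with the highest mesothelium scores, given above, were all of low intake. Without them, chosen after seeing the data, complement was at -0.23 and the matrix list at -0.15, both still called. Macrophages (-0.19) and mesothelium (-0.05) were no longer called, and smooth muscle turned to -0.024. Lipogenesis turned to 0.12 without HGHI 3 and LGHI 1, which had its lowest scores (-1.54 and -1.60), and was at -0.10 and -0.17 without each alone. Without LGLI 4 alone the macrophage list was at -0.34, still called, and without LGHI 1 alone the liver list was at 0.12. Other calls also ended without single steers: interferon without HGLI 4 (-0.07), matrix without LGHI 1 (-0.22), mesothelium without any of 5 steers (-0.54 without HGLI 3), clock without any of 6 (-0.12 without LGHI 2), smooth muscle without any of 6 (0.18 without HGHI 3) and liver without any of 8 (0.03 without LGHI 3).

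The interaction asked whether the gain difference depended on intake. Among genes with an unadjusted p under 0.01, those with the largest positive values had their lowest mean in LGHI. PTI, the pancreatic trypsin inhibitor, was at 12.48 ± 1.73 in LGHI against 15.59 ± 1.25 in LGLI, 14.54 ± 1.49 in HGLI and 15.09 ± 0.67 in HGHI, an interaction of 3.66 ± 1.20. LGHI 1 was far below the other LGHI steers for PTI, at 10.5 against 13.3 and 13.6. Without LGHI 1 and HGHI 3, the steers lowest for lipogenesis, the PTI interaction was 2.79. C29H11orf24 (1.72 ± 0.39), the basement membrane protein NID2 (1.65 ± 0.54), the small heat shock protein HSPB6 (1.57 ± 0.48) and GPX7, a peroxidase of the endoplasmic reticulum (1.46 ± 0.48), had the same sign. The opposite sign was found for RXFP1, the relaxin receptor (-1.61 ± 0.41), OR5H33 (-1.23 ± 0.35), OR1A1C (-1.21 ± 0.32), the kinase SNRK (-1.15 ± 0.38) and PRDM9 (-1.12 ± 0.35). RXFP1 was highest in HGLI (8.80 ± 0.53) and lowest in HGHI (7.15 ± 0.39). Adjusted p was 0.936 for each of the 10 genes. With limma, 0 probes passed and 1384 had an unadjusted p under 0.05, against 1339 by chance.

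For 4 lists the gain difference was more positive at high than at low intake in camera, each with adjusted p = 0.996 with an estimated correlation. These were lipogenesis (0.70, 15 of 17 members in that direction, for example MLXIPL, a transcription factor of lipogenesis, at 0.85 ± 0.40), preadipocyte and fibroblast markers (0.56, 14 of 15, FAP at 2.16 ± 0.85), extracellular matrix (0.45, 22 of 28, biglycan, BGN, at 1.57 ± 0.68) and cholesterol synthesis (0.61, 14 of 16, lanosterol synthase, LSS, at 1.56 ± 0.81). In each, 0 members passed adjusted over the list alone. Camera's adjusted p was 0.0195, 0.0195, 0.0243 and 0.0326. Leaving out the lowest 25% of probes ended all 4 calls, as did the array standard deviation as a covariate. Without LGHI 1 the 4 calls also ended, at 0.25 for lipogenesis, 0.28 for preadipocytes, 0.30 for matrix and 0.64 for cholesterol synthesis. They ended without LGLI 1 too, at 0.64, 0.50, 0.36 and 0.55. Over all 15 single steers, leaving 1 out ended the call of lipogenesis in 5 cases, of preadipocytes in 3, of matrix in 4 and of cholesterol synthesis in 7, among them preadipocytes (0.36) and matrix (0.33) without HGHI 1, matrix (0.47) and cholesterol synthesis (0.52) without HGLI 3, lipogenesis (0.53) and cholesterol synthesis (0.39) without LGLI 2 and cholesterol synthesis (0.57) without LGHI 2. Lipogenesis and cholesterol synthesis were at 0.44 and 0.30 without HGHI 2, at 0.39 and 0.35 without HGHI 4 and at 1.29 and 1.03 without HGHI 3, where both were called. LSS was at 1.03 without HGHI 4.

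HGLI and LGHI, the groups that gained most and least for their intake, were compared with 0 of 26773 probes past the threshold, and the named genes are those with the largest differences at an unadjusted p under 0.01. The chloride channel subunit GLRB, of the glycine receptor, was 4.42-fold higher in HGLI (2.14 ± 0.59), and MYOC, which encodes the secreted glycoprotein myocilin, 3.91-fold (1.97 ± 0.39), at 10.98 ± 0.14 in HGLI and 9.02 ± 0.15 in LGHI. CITED2, a transcriptional co-regulator, was 3.26-fold higher (1.70 ± 0.42), PDLIM3 2.99-fold (1.58 ± 0.28) and SERPING1 2.68-fold (1.42 ± 0.40). SNCG was 3.78-fold lower in HGLI (-1.92 ± 0.44), at 7.43 ± 0.68 against 9.35 ± 0.16 in LGHI. IL18BP was 3.59-fold lower (-1.84 ± 0.50), the vasodilator peptide gene ADM 2.59-fold (-1.38 ± 0.45), ANGPTL4 2.56-fold (-1.36 ± 0.39) and OR5H33 2.41-fold (-1.27 ± 0.26). Without LGHI 1 the IL18BP difference was -1.18. In each of these 10 genes the 4 HGLI steers did not overlap the 3 LGHI steers. That held for 3214 probes (1285 higher and 1929 lower), where chance gives 1530, or 5.71% of the probes. Adjusted p of the 10 genes lay between 0.167 and 0.285. With limma 0 probes passed, 3322 had an unadjusted p under 0.05, and 908 had one under 0.01 (279 higher, 629 lower, 268 by chance). In a fit to these 7 arrays alone MYOC passed (adjusted p = 0.0135), along with PRRX1 (1.40) and 24 unnamed probes with identical values, and over the 27 alternatives the lowest adjusted p ran from 0.0135 to 0.688.

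Camera placed 11 lists higher and 1 lower in HGLI with its preset correlation. None of the 12 was called when the correlation was estimated (lowest adjusted p = 0.582 with an estimated correlation). Preadipocyte and fibroblast markers differed by 0.71, 13 of 15 higher, and 4 passed adjusted over the list alone: the platelet-derived growth factor receptors PDGFRA (0.80 ± 0.27) and PDGFRB (0.63 ± 0.21), CD34 (0.72 ± 0.26) and DPT (1.21 ± 0.36). Lipogenesis genes were higher by 0.96 (16 of 17), complement by 0.89 (16 of 18, SERPING1 past the threshold adjusted over the list alone), smooth muscle by 0.72 (9 of 12), matrix by 0.47 (21 of 28) and oxidative phosphorylation by 0.45 (29 of 30, for example SDHC of complex II at 0.48 ± 0.20). Oxidative stress genes (0.37, 20 of 23, GPX1 at 0.55 ± 0.16), glycolysis (0.32, 17 of 20, GAPDH at 0.65 ± 0.22), the unfolded protein response (0.26, 12 of 17), interferon response (0.24, 20 of 26) and ribosomal proteins (0.18, 20 of 27) were higher as well. Within these, DNAJC3 (0.79 ± 0.19) and IFIT5 (0.93 ± 0.21) passed adjusted over the list alone, and over all probes 0 members of any list passed. Erythroid markers were lower by a mean difference of -0.23, 8 of 9 lower, including HBA, alpha haemoglobin (-0.59 ± 0.24). Of these faint markers 0 lay above the median probe. Over all probes in bins at median levels of 6.86 and 7.29, HGLI minus LGHI had medians of -0.13 and -0.10.

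Camera's adjusted p was 7.0e-06 for oxidative phosphorylation and preadipocytes, 0.000203 for lipogenesis, 0.00142 for matrix, 0.00225 for oxidative stress and complement, 0.00389 for interferon, 0.00413 for ribosomal proteins, 0.00982 for glycolysis, 0.0135 for the unfolded protein response, 0.0162 for smooth muscle and 0.0311 for erythroid markers. None was called with an estimated correlation: adjusted p = 0.582 for preadipocytes, matrix, oxidative stress, the unfolded protein response and erythroid markers, and 0.609 for the others. The 35 possible splits of 4 against 3 steers allow no exact permutation p below 0.0286, and the lowest after adjustment was 0.219. Without LGHI 1, calls ended for lipogenesis (0.51), glycolysis (0.10) and matrix (0.31), without HGLI 3, the steer highest for mesothelium, for complement (0.40), and without HGLI 4 the interferon difference turned to -0.012. Without LGHI 1, oxidative phosphorylation fell to 0.27 and preadipocytes to 0.44, both still called, GAPDH was at 0.42 and interferon at 0.37, and interferon was at 0.40 without HGLI 2. Calls also ended without LGHI 3 for smooth muscle (0.39; also without any of 3 HGLI steers), interferon (0.14) and ribosomal proteins (0.12), without HGLI 2 for the unfolded protein response (0.19) and without HGLI 1, LGHI 2 or LGHI 3 for erythroid markers (-0.19 each). With the array standard deviation as a covariate, preadipocyte, complement and smooth muscle calls were kept, lipogenesis came to 0.11, and oxidative phosphorylation (-0.0016), glycolysis (-0.042) and erythroid markers (0.0070) changed sign.

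**Figure D2:**
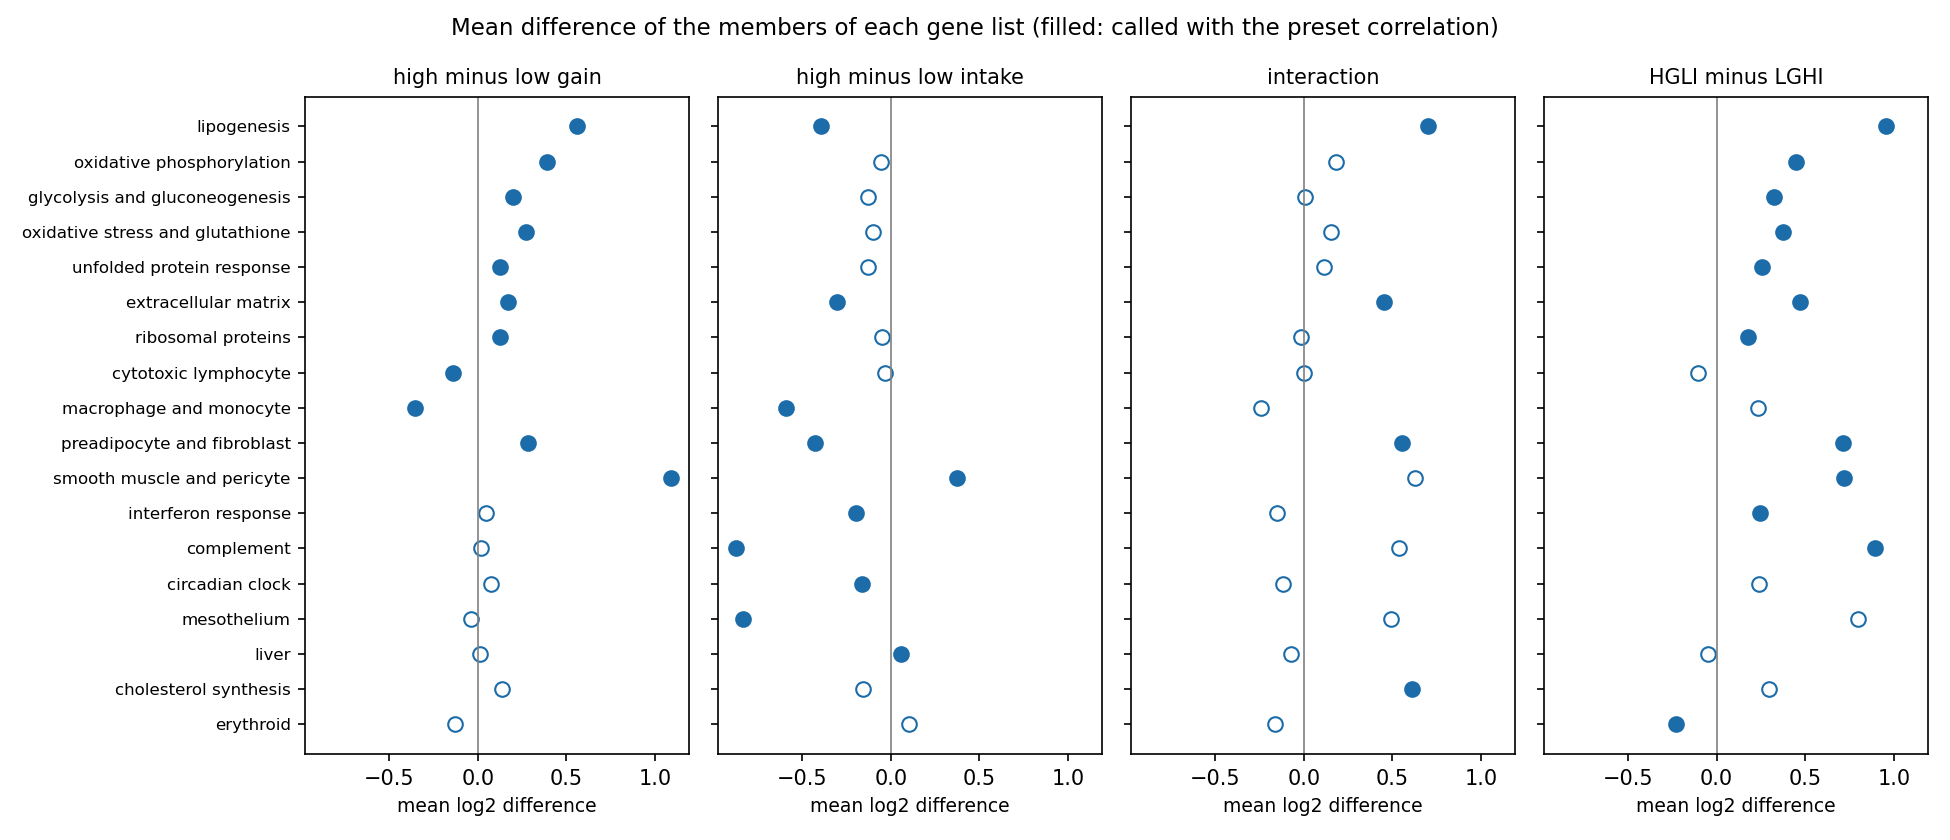
Mean log2 difference of the members (horizontal axis) of each of the 18 gene lists called in any comparison (vertical axis), for gain, intake, the interaction and HGLI minus LGHI, with filled points for lists called by camera at the preset correlation. Smooth muscle stands out for gain (1.09), complement (-0.87) and mesothelium (-0.84) have the lowest values for intake, and no list was called with an estimated correlation.

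**Figure D3:**
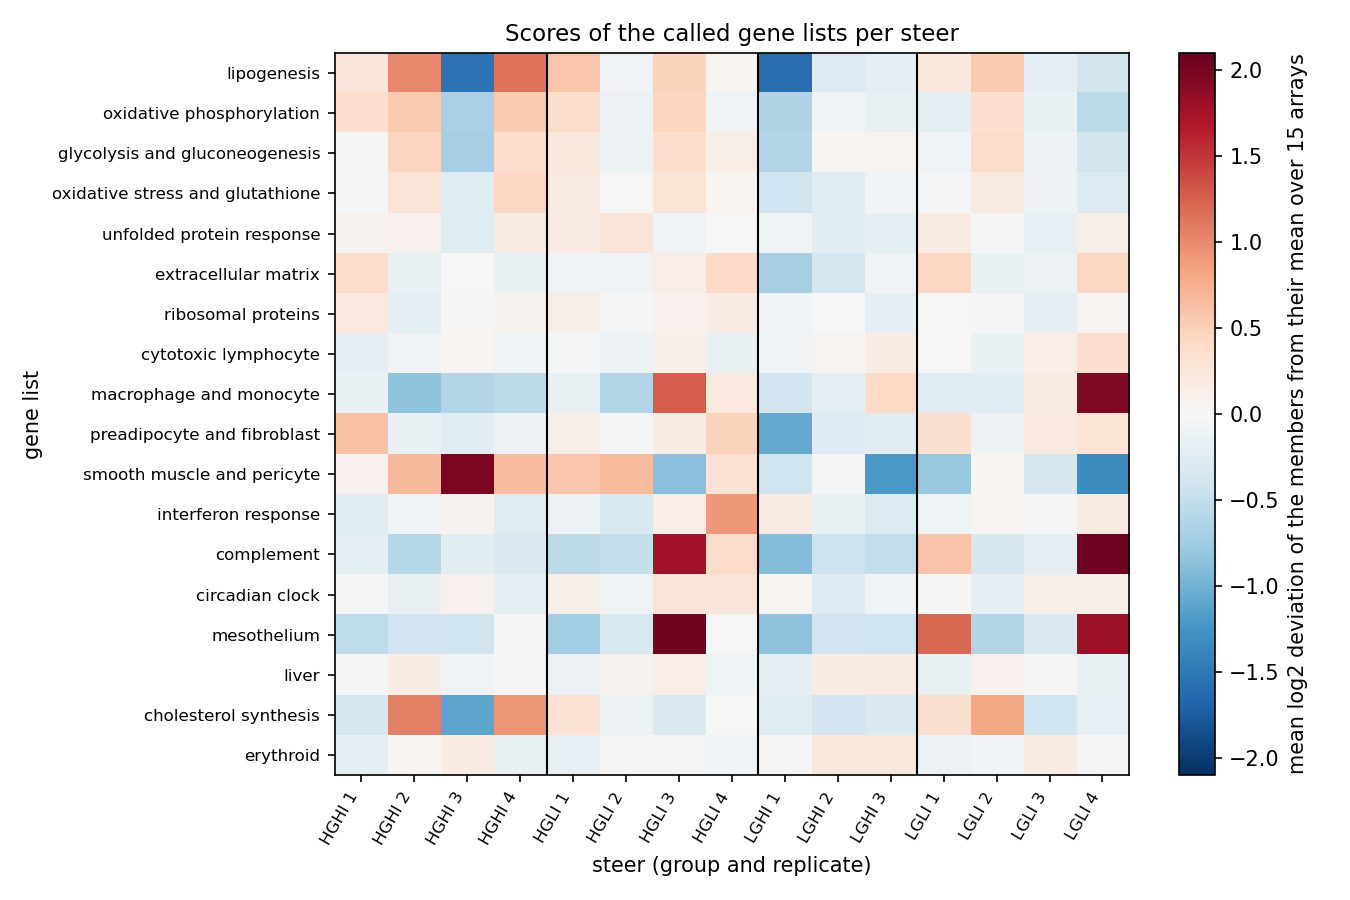
Score of the 18 called lists (vertical axis; mean log2 deviation of the members from their mean over all arrays, as colour) in each of the 15 steers (horizontal axis). HGLI 3, LGLI 1 and LGLI 4 stand out for mesothelium (2.02, 1.21 and 1.81), and HGHI 3 and LGHI 1 have the lowest lipogenesis scores (-1.54 and -1.60).

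Among the pairs of groups that shared a trait level, HGHI and LGHI (gain at high intake) differed in 2927 probes at an unadjusted p under 0.05, and LGHI and LGLI (intake at low gain) in 2380. HGLI and LGLI (gain at low intake) differed in 1002 and HGHI and HGLI (intake at high gain) in 755, both below the 1339 that chance gives. With limma 0 probes passed in each of the 4, with lowest adjusted p of 0.232, 0.187, 1 and 0.865. Whether gain mattered more at high than at low intake is the interaction, for which 0 probes passed. The contrasts with the larger counts were those that include LGHI.

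Of the fixed panel of 16 adipose genes, 0 passed in any of the 4 main comparisons, over all probes or adjusted over the list alone, where the lowest adjusted p was 0.584 for gain, 0.623 for intake, 0.756 for the interaction and 0.311 for HGLI against LGHI. Fatty acid synthase (FASN) was at 17.57 ± 0.94 in HGLI, 17.32 ± 1.88 in HGHI, 16.96 ± 0.71 in LGLI and 15.60 ± 2.21 in LGHI. ACACA lay between 15.04 and 15.89 in 3 groups and at 13.70 ± 1.60 in LGHI. LGHI 1 was far below the other LGHI steers for both genes, at 11.84 for ACACA (14.62 and 14.63) and 13.05 for FASN (16.85 and 16.91). Without it the difference between HGLI and LGHI went from 1.83 to 0.91 for ACACA and from 1.97 to 0.70 for FASN. SCD, stearoyl-CoA desaturase, was at 19.68, the ceiling of the arrays, in all HGLI and LGLI steers and in HGHI 1, HGHI 2 and HGHI 4, so its means in these 3 groups are only lower bounds. LPL (19.15 to 19.22), CD36 (19.27 to 19.41), ADIPOQ (19.05 to 19.51) and FABP4 (18.59 to 19.20) were close to that ceiling too. Leptin (LEP) lay between 13.90 and 14.48, PPARG between 13.78 and 14.12, and the lipases LIPE between 13.70 and 14.51 and PNPLA2 between 15.35 and 15.96. Of the inflammatory genes, TNF lay between 5.48 and 5.55, IL6 between 6.41 and 7.09, CCL2 between 8.89 and 9.82 and the macrophage marker CD68 between 10.15 and 11.60. UCP1, the uncoupling protein of thermogenic fat, ranged from 5.85 ± 0.33 in LGLI to 6.77 ± 1.66 in HGLI.

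The other 28 lists were called in none of the 4 main comparisons, and the ranges here are of their mean differences over these. Adipocyte markers ran from -0.04 to 0.05, adipogenesis regulators from -0.05 to 0.14, adipokines from -0.21 to 0.01, triglyceride synthesis from -0.06 to 0.12, lipolysis from -0.33 to 0.19, fatty acid uptake from -0.10 to 0.07, fatty acid oxidation from -0.09 to 0.17, thermogenic genes from -0.13 to 0.06, the insulin and growth hormone axis from -0.16 to 0.26 and steroid metabolism from -0.05 to -0.01. Inflammatory cytokines ran from -0.05 to 0.16, MHC class I presentation from -0.12 to 0.16, MHC class II from -0.23 to -0.04, handling stress genes from -0.10 to 0.35 and cell cycle genes from -0.03 to 0.0043. Of the leukocyte markers, T cells ran from -0.04 to 0.09, B cells from -0.10 to 0.04, plasma cells from -0.11 to 0.19, lymph node stroma from -0.02 to 0.20, neutrophils from -0.04 to 0.07, dendritic cells from -0.05 to 0.05 and mast cells from -0.11 to 0.48. Endothelium ran from -0.21 to 0.16, lymphatic endothelium from -0.21 to 0.55, intestinal epithelium from -0.16 to 0.05, pancreas from -0.03 to 0.01, nerve and glia from 0.0046 to 0.11 and skeletal muscle from -0.15 to 0.07. Single steers spread more widely than these group differences, with adipocyte scores from -1.12 in HGHI 3 to 0.63 in LGLI 2. The lowest camera adjusted p among these lists was 0.0652, for endothelium. Mean, median and test had the same sign in all 37 calls and differed in sign in 33 of the 184 tests.

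The values of the LGHI arrays were on average less widely spread than those of the other arrays, with overlap. The standard deviation over probes was 2.420 in the 3 LGHI arrays and 2.488 in the other 12, a difference of -0.067 (exact permutation p = 0.00879 over 455 splits, chosen after seeing the data). HGHI 3 (2.419) and LGLI 3 (2.435) lay within the range of the LGHI arrays, 2.402 to 2.448. Over 2677 probes at a median level of 6.38, HGLI minus LGHI had a median of -0.15, and over 2677 probes at a median level of 11.1 a median of 0.13. After quantile normalization these medians were -0.02 and 0.01. The median level was 6.34 for 815 olfactory receptor probes, 7.42 for the cytotoxic lymphocyte list, 7.08 for the liver list and 7.14 for the erythroid list. It was 11.65 for oxidative phosphorylation, 12.56 for glycolysis, 14.17 for lipogenesis and 15.90 for ribosomal proteins. The first principal component held 17.4% of the variance and the second 15.9%.

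**Figure D4:**
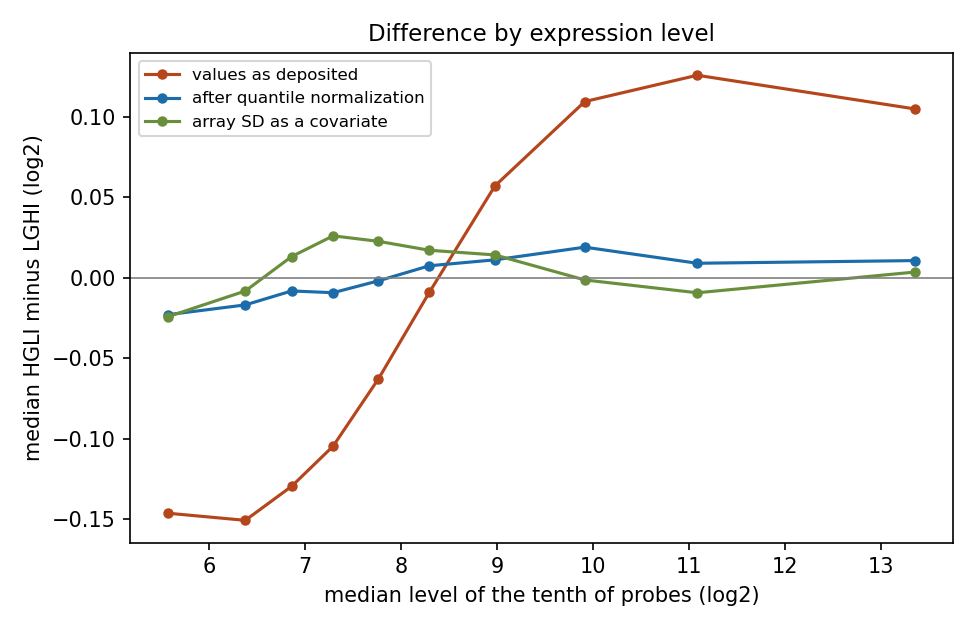
Median log2 difference between HGLI and LGHI (vertical axis) of the probes in 10 bins of mean level (horizontal axis), for the deposited values, after quantile normalization and with the array standard deviation as a covariate. The deposited values run from -0.15 in low bins to 0.13 in high bins, and the other lines stay close to 0.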

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

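All tests of the smooth muscle, complement and olfactory receptor patterns below were chosen after these patterns were seen, and the scaling and mesothelium tests also after their own values, while the limits of the smooth muscle test within groups, of the olfactory receptor test and of the counts over other splits were set before their values were computed.

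Steers were regrouped at random to learn how often other groupings give as many results. For gain, 9 of 100 splits gave as many probes with an unadjusted p under 0.01 as the real 588 (highest other 1474), for intake 19 of 100 (382, highest other 929) and for the interaction 33 of 100 (273, highest other 1204), so chance cannot be excluded for these counts. For HGLI against LGHI, 1 of 35 splits, the real split itself, gave 908 (highest other 887), and for LGHI against LGLI 1 of 35 gave 599 (highest other 490). No other split matched these 2 counts, but 1 of 35 is the smallest share the design can give. There was no adjustment over the 12 counts tested, and 908 lies close to 887, so chance is not excluded for either contrast. In both, 0 probes passed the adjusted threshold. Chance cannot be excluded for HGHI against LGHI (5 of 35, 776, highest other 1862), HGLI against LGLI (23 of 35, 139, highest other 634) or HGHI against HGLI (33 of 35, 97, highest other 528). The split with 1862 probes put HGHI 3 with the 3 LGHI steers. The gain split with 1474 probes also put these 4 steers on one side. At the adjusted threshold, the most probes called in any other split were 241 for HGHI against LGHI and 178 for gain. Whether these highest adjusted counts came from the same splits was not recorded. The steers on each side were read off after the counts were seen, for the splits with the highest counts. Both splits keep the LGHI steers together, so they cannot tell a structure apart from the groups from LGHI plus 1 unusual array. Neither was tested. The number of lists called was matched by 56 of 100 splits for gain (11 lists, highest other 21), 60 of 100 for intake (10, highest other 22), 96 of 100 for the interaction (4, highest other 23) and 7 of 35 for HGLI against LGHI (12, highest other 16). Chance cannot be excluded for any of these list counts.

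Smooth muscle markers were 1.09 higher in the high gain steers in camera (adjusted p = 0.689 with an estimated correlation). Scaling of the arrays is argued against, since 0.967 of the difference was left under the correction that removed most (1.06 after quantile normalization, 1.56 with the array standard deviation as a covariate). A varying amount of smooth muscle in each piece of fat remains a candidate explanation. Within groups, the 12 members varied together with a mean pairwise correlation of 0.519, just above the limit of 0.5 set beforehand. The 95th percentile of 10000 random lists was 0.0796. Markers of the same cell type also vary together when they are regulated together, so this correlation cannot tell amount from regulation. Vessel walls of fat also hold smooth muscle. Mean endothelium scores were 0.03 in HGHI, -0.03 in HGLI, 0.15 in LGHI and -0.12 in LGLI, without a rise in both high gain groups. Of the 12 smooth muscle markers, 11 lay above the median probe, and RGS5 was highest at 14.48. Levels of different probes are not strictly comparable and the background is unknown, so this does not show where the signal comes from. Whether gain goes with more smooth muscle in this fat, or the dissection caught more vessel or gut wall in some steers, stays open and untested.

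Complement genes were lower in the high intake steers by a mean difference of -0.87, along with mesothelium and macrophage markers, all in camera (adjusted p = 0.627, 0.791 and 0.757 with an estimated correlation). Scaling is argued against, with 0.947 of the difference left (-0.86 and -0.83 under the 2 corrections). Mesothelium in 3 of the samples is a candidate explanation for most of it: without HGLI 3, LGLI 1 and LGLI 4, 0.261 of the difference was left (-0.23, still called by camera), although removing 3 extreme steers of the low intake side shrinks any difference they share. Of the 16 mesothelium markers, 6 lay above the median probe over all steers and PRG4 was highest at 11.10, although levels of different probes are not strictly comparable. The macrophage and complement lists have 3 genes in common. A difference between the intake groups themselves stays open and untested.

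Olfactory receptor genes, a family singled out after the data were seen, had a median difference of -0.15 between HGLI and LGHI, with 75.7% of 815 probes lower in HGLI. Other probes of the same level had a median of -0.14, so the excess was -0.0101 (bootstrap interval -0.03 to 0.01). The median of the family therefore matches that of other faint probes and goes with the on average narrower range of values on the LGHI arrays, shared by HGHI 3 and LGLI 3. In bins 1 to 5 of level the median over all probes ran from -0.15 to -0.06. Single genes such as OR5H33 (-1.27) differed more. After quantile normalization the median was -0.04, and with the array standard deviation as a covariate it turned to 0.04. Whether the narrower range is technical or reflects the tissue of these steers was not tested.

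For 4 lists the gain difference was larger at high than at low intake: lipogenesis by 0.70, cholesterol synthesis by 0.61, extracellular matrix by 0.45 and preadipocyte and fibroblast markers by 0.56. Each of the 4 was found by the interaction contrast in camera, and for each the adjusted p was 0.996 with an estimated correlation.

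In groups of 4, single steers stood apart from the other 3 in 38 of 486 cases, each described by its gap to the nearest steer as a share of the group's range; the test is Dixon's at its 95% critical value. Chance marks about 1 case in 20, or 24.3 here, and the genes are not independent. Close to the array ceiling the share can be set by how tightly the other 3 values are pressed together. It carries no information for SCD, lowest in HGHI 3 (0.9997, the others at the ceiling), and little for LPL (0.999; 19.37 against 19.17) and DCN (0.969; 19.26 against 19.11), both highest in HGLI 4. The cases of ADIPOQ, of CD36 and of DCN in LGLI also lay close to the ceiling. HGHI 3 was lowest of its group for ADIPOQ (0.895; 18.20 against 19.28 to 19.41), ATP5F1B (0.840) and the oxidative phosphorylation list (0.834), and highest for IL6 (0.889; 8.94 against 6.36 to 6.65), PLN (0.860) and OR8B1AN (0.830). HGLI 3 was lowest for RGS7 (0.939), CD36 (0.878), PLN (0.871) and SYNM (0.851) and highest for ASNS (0.917), ERRFI1 (0.884), CD5L (0.833; 14.34 against 9.56 to 10.36) and PGK1 (0.830). LGLI 4 was highest for CSF1R (0.992), SERPING1 (0.868) and CD5L (0.867; 15.36 against 9.20 to 10.02) and lowest for CD36 (0.916) and UQCRB (0.907). HGHI 4 was highest for ERRFI1 (0.914), KRT19 (0.865) and LRRN4 (0.849) and lowest for HERC6 (0.872). HGLI 4 was highest for IFI35 (0.853) and lowest for CA1 (0.880). Also apart were HGLI 1 (NSDHL highest, 0.874; HBA lowest, 0.896), HGLI 2 (BGN lowest, 0.899), and HGHI 1, highest for UCP1 (0.935; 7.68 against 5.61 to 5.74) and for the preadipocyte and fibroblast list (0.875). In LGLI, steer 2 was lowest for DCN (0.8291) and PDGFRA (0.862) and highest for MLXIPL (0.972), and steer 3 was lowest for PFKP (0.831) and CST7 (0.865).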

How the results depend on the processing

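The fits without the 3 steers highest for mesothelium, without the 2 lowest for lipogenesis and with the array standard deviation as a covariate were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the replicate numbers only name arrays of separate steers, and shared sires or pens are not given in the sources used here. For gain, where 0 probes passed, 1 passed with array centring, 1 with gain as the only factor, 1 without the 3 mesothelium-high steers, and 2 with only probes of 1 symbol (fewer probes tested) or at the threshold of 0.1. For HGLI against LGHI, 3 passed without moderation, 3 without the 2 lipogenesis-low steers and 26 in a fit to the 2 groups alone, and for HGHI against LGHI 3 passed without the 2 lipogenesis-low steers. Leaving out single steers gave 0 to 1 probes for gain (1 without HGLI 4 or LGLI 4), the interaction (1 without LGHI 3), HGLI against LGHI (1 without LGHI 1) and HGHI against LGHI (1 without LGLI 3). For intake and the other contrasts 0 probes passed in every alternative; the lowest adjusted p for intake ran from 0.153 to 0.999, with 1886 probes at an unadjusted p under 0.05 in limma. With an estimated correlation and with fry, 0 lists were called in gain, intake, interaction and HGLI against LGHI, in place of 11, 10, 4 and 12. The number for gain was 6 with quantile normalization, 7 without the lowest 25% of probes and 4 with the array standard deviation as a covariate. For the interaction it was 2, 0 and 1 in these settings and 2 without the 3 mesothelium-high steers. Without single steers it ran from 7 (without LGHI 1) to 12 for gain, 6 (without LGLI 1) to 15 (without HGHI 4) for intake and 0 (without LGLI 1) to 8 (without HGLI 2) for the interaction. Of the 10 intake calls, quantile normalization kept 8 and the array standard deviation as a covariate 6, and of the 12 calls between HGLI and LGHI they kept 7 and 3.

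Among the named genes and called lists, directions turned in a few cases. Turns of the other panel genes were not tallied, and some of these occur without a single steer. Examples are the FASN interaction (1.11) without LGHI 1 and the IL6 gain difference (0.05) without HGHI 3, which both become negative. Without the 3 mesothelium-high steers, CNN1 for intake was at -0.15 and the smooth muscle list at -0.024, and without the 2 lipogenesis-low steers the lipogenesis list for intake was at 0.12. The interferon list for HGLI against LGHI ran from -0.012 without HGLI 4 to 0.40 without HGLI 2. With the array standard deviation as a covariate, the gain differences of DDIT3 (-0.0084), NCR1 (0.017) and the glycolysis list (-0.027) turned. So did the HGLI against LGHI differences of CA1 (0.18) and of the oxidative phosphorylation (-0.0016), glycolysis (-0.042) and erythroid (0.0070) lists. The cause was not tested, beyond the fewer steers or probes by construction. Over the 37 list calls, alternatives kept 216 results on the same side, ended 148 calls and turned 6, and leaving out single steers kept 462, ended 92 and turned 1. Over the named genes, 2161 results under alternatives kept direction and side, 4 passed and 4 turned. No background level was known, so what faint probes can show is not limited by a stated signal over background.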

Other observations

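In some steers the values of single genes lay far above those of the other steers. UCP1, which marks thermogenic fat, was at 8.996 in HGLI 2, 7.92 in LGHI 2 and 7.68 in HGHI 1, and between 5.06 and 6.85 in the other 12 steers. The score of the thermogenic list, of which UCP1 is 1 of 14 members, was 0.14, 0.30 and 0.07 in these 3 steers, the highest of each one's group. Over the other 13 members, a score computed after seeing the data, it was -0.055, 0.20 and -0.027, and of the 3 LGHI 2 alone was highest in its group. CD5L, a macrophage protein, was at 15.36 in LGLI 4 and 14.34 in HGLI 3 and between 8.83 and 10.36 in the other 13.

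These last 2 steers and LGLI 1 also had the highest levels of keratin 19 (KRT19; 12.02, 12.47 and 10.64 against 6.03 to 7.80), mesothelin (MSLN; 11.21, 11.64 and 10.57 against 7.43 to 8.39) and C3 (17.71, 17.62 and 16.13 against 9.13 to 13.65) among the 15. Keratin 19 and mesothelin are markers of the mesothelium, the cell layer that covers visceral fat. These genes are named after their values were seen, and no group label separates the 3 steers from the rest, except that all are of low intake.

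HGHI 3 stood apart from the other HGHI steers in several measures, some of them close to LGHI steers and others not. Its standard deviation over probes was 2.419, against 2.448, 2.402 and 2.410 in LGHI and 2.497 to 2.533 in the other HGHI steers. Its lipogenesis score was -1.54, against 0.26 to 1.14 in the other HGHI steers and -1.60, -0.28 and -0.21 in LGHI. Its smooth muscle score of 1.98 was the highest of all, whereas LGHI ran from -1.21 to -0.02. It had the lowest array weight (0.488) and a median correlation of 0.972 with its own group. Whether this array carries the right group label, or its piece of fat differed in makeup, was not tested. A wrong label would bear on every comparison that includes HGHI or the true group of the steer, and on the others through the shared estimate of the spread. Without this array 0 probes passed in each of the 8 contrasts. The lowest adjusted p of HGLI against LGHI in limma was then 0.0809, in place of 0.167. With the preset correlation, camera called 12 lists for gain, 9 for intake and 5 for the interaction.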
